A study of Mus musculus with 115 samples.

How the data were processed

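Gene expression was measured in mammary fat pads of 115 untreated female mice aged 8 weeks, with 1 Affymetrix array per mouse. Per the labels, each mouse came from a backcross in which hybrids of the laboratory strain FVB/N and a Mus spretus strain (Spret/Ei) were mated to FVB/N. Such mice carry either FVB/N alleles alone or 1 Mus spretus allele at each autosomal locus, so they differ from each other genetically although none was treated. Total RNA was labelled with biotin, per the labels' protocols.

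The deposited values are on the log2 scale and were made with the robust multi-array average (RMA) method and the oligo package, per the submitters' processing notes. The versions of these tools are not given in the sources used here. The value table held 28204 probe sets. Of these, 21141 had 1 gene symbol in the platform annotation, 1881 had several and 5182 had none. Symbols were updated by gene identifier through the RefSeq gene table of assembly GRCm38.p6, which matched 21111 of the probe sets with 1 symbol and left 18772 distinct genes. No build was named for the arrays, so that table was used only for names and for which genes lie near each other. For a gene with several probe sets, the one with the highest mean was used in gene lists. In the value table, 654 probe sets had values equal to those of another probe set on each array.

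The labels place each mouse in 1 of 3 lymph clusters and on 1 of 2 array plates, and do not say how the clusters were made. Cluster 1 held 44 mice, cluster 2 held 61 and cluster 3 held 10. Plate 1 held 93 arrays and plate 2 held 22. Replicates were numbered in accession order and were not paired. Array medians lay between 6.16 and 6.45, and correlations between pairs of arrays between 0.928 and 0.992, so no array was a copy of another. For arrays, their number limits the precision.

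Tests were run with limma 3.58.1 in R 4.3.3, by linear models with empirical Bayes moderation and Benjamini-Hochberg adjustment over all probe sets, and a call was an adjusted p under 0.05. One model held lymph cluster and array plate, another added the Hipk2 value of each mouse, and the last tested on clusters 1 and 2 (105 arrays) whether the slope on Hipk2 differed. The slope is the log2 change of a gene per log2 unit of Hipk2, and Hipk2 itself was left out of the genes tested. The 27 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it. For the lymphoid lists the camera p between clusters 2 and 1 was also computed in 99 random splits of the mice, a test added after the result was seen. Correlations of Hipk2 with 8 adipocyte genes were computed within each cluster, with 100000 two-sided permutations, or every permutation (an exact test) where fewer than 10 mice were used. Calls among genes within 20 Mb of Hipk2 were compared with other genes by Fisher's exact test, two-sided. All probe sets were tested, with no filter on dim ones in the first instance.

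Groups, designs, gene lists, most alternatives and the rule for named genes were chosen before the data were examined. The rule took Hipk2, the 8 largest rises and 8 largest falls among calls in each cluster comparison and for the slope, up to 4 members of each list with the smallest p, the 4 largest rises and 4 largest falls for plate, and the 8 correlation genes. Predicted genes, RIKEN genes and antigen receptor segments were left out of the largest rises and falls. To keep the text short, only the first 2 members per list were named, and for the clusters only those of 4 lists. This narrowing was made after the values were seen and followed the order of the rule.

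Each model was tested on simulated data in which 200 genes were changed by known amounts. Changes of 0.5 on the log2 scale were recovered for 95.7% of genes between clusters 2 and 1, 77.6% between clusters 3 and 1, 89.7% between clusters 3 and 2, 95.2% between plates, 96.9% for the slope and 43.5% for the slope difference, over 28204 probe sets for the groups and 28203 for the slopes. Changes of 0.25 were recovered for 67.3%, 27.3%, 32.9%, 51.5%, 57.4% and 5.6% of genes in the same order. Unchanged probe sets made up 9 of 188, 6 of 141, 33 of 179, 25 of 188, 1 of 170 and 1 of 96 calls, so the share of false calls passed the nominal level between clusters 3 and 2 and between plates. Genes with 2 separated levels were sought with equal-variance mixtures in mclust 6.1.1 on values corrected for cluster and plate. Figures were drawn with matplotlib 3.10.9. Alternatives left out the plate term, split the plates, dropped dim probe sets, normalized again, weighted arrays, changed the moderation or used ranks.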

Results

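Mammary fat pads of 115 backcross mice were profiled, 44 in lymph cluster 1, 61 in lymph cluster 2 and 10 in lymph cluster 3. Plate 1 carried 34, 50 and 9 mice of the clusters and plate 2 carried 10, 11 and 1. Each mouse was a separate animal. The median probe set varied between mice with an SD of 0.238 on the log2 scale. Hipk2, a nuclear serine/threonine kinase named in the title of the series, was read by 1 probe set with a mean log2 value of 10.72 ± 0.348 (SD, n = 115), at the 96.3rd percentile of probe sets. Its values ranged from 9.83 to 11.49.

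The first question was how Hipk2 and other genes differed between the lymph clusters. Hipk2 was 10.73 ± 0.344 (SD, n = 44) in cluster 1, 10.71 ± 0.362 (SD, n = 61) in cluster 2 and 10.74 ± 0.303 (SD, n = 10) in cluster 3. The difference was −0.026 for cluster 2 against 1 (95% interval −0.163 to 0.111), 0.009 for 3 against 1 (−0.234 to 0.252) and 0.035 for 3 against 2 (−0.201 to 0.271). Each was smaller than the spread between mice, and limma's adjusted p was 1.000 for all 3. These values carry a limit: probe sets in general differed less between the clusters than in random splits of the mice (0.0142% with an unadjusted p under 0.05 for 2 against 1, against at least 1.60%), so small differences between clusters were not particular to Hipk2. If the values were adjusted for cluster before deposit, which no source used here records, these intervals do not measure a biological difference in Hipk2.

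In cluster 2 against cluster 1, all 18 measured B cell genes, 16 T cell genes and 9 genes of lymph node stroma and high endothelium had higher mean values, although no single gene passed the test. The mean of the B cell list was 0.224 higher (SE 0.12), that of the T cell list 0.227 higher (SE 0.12) and that of the lymph node stroma list 0.160 higher (SE 0.081). Ms4a1, which encodes the B cell antigen CD20, differed by 0.36 (SE 0.17) and Cd79a, part of the B cell receptor, by 0.29 (SE 0.15). Trat1 and Cd3e, of the T cell receptor complex, differed by 0.26 (SE 0.13) and 0.27 (SE 0.14). Glycam1, which high endothelial venules make, differed by 0.39 (SE 0.20) and the chemokine Ccl19 by 0.28 (SE 0.14). These differences were smaller on plate 1 than on plate 2. The B cell list mean differed by 0.12 (SE 0.14, 50 against 34 mice) on plate 1 and by 0.62 (SE 0.16, 11 against 10 mice) on plate 2, the T cell list mean by 0.16 (SE 0.14) and 0.51 (SE 0.17), and the lymph node stroma list mean by 0.094 (SE 0.093) and 0.42 (SE 0.13). Ms4a1 differed by 0.21 (SE 0.20) on plate 1 and 0.97 (SE 0.23) on plate 2, and Cd79a by 0.16 (SE 0.18) and 0.81 (SE 0.19), with a limma adjusted p of 1.000 for both on plate 1 and 0.255 for both on plate 2. Whether the plates differed in these values was not tested. The adipocyte regulator Pparg differed by −0.031 (SE 0.063) and the fatty acid transporter Cd36 by −0.018 (SE 0.043).

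Camera called 11 of the 27 lists between clusters 2 and 1, 7 higher and 4 lower. The adjusted p was 1.07e-60 for B cells and 1.01e-59 for T cells, and 5.63e-05 for both with an estimated correlation. The lymph node stroma list had an adjusted p of 6.88e-19, and 1.35e-04 with an estimated correlation. The lists of NK and cytotoxic cells and of dendritic cells were also called higher, with an adjusted p of 0.0372 each with an estimated correlation, and the other 6 calls were lost with it. Camera sets a list against the other genes, and those differed less between these clusters than in random splits of the mice. At the preset correlation 48 of 99 random splits gave the B cell list and 57 the T cell list an unadjusted p under 0.05, and with an estimated correlation 2 and 3 did. The real split had the smallest p of 100 for both lists, but 5 of 100 splits, the real one included, had a T cell median difference as high as the real 0.222, against 1 for the B cell median of 0.228. The labels do not say whether the clusters were made from these expression values. If they were, a small p in the real split was fixed in advance and is no independent evidence of a lymphoid difference. On plate 1 alone the adjusted p at the preset correlation was 1.67e-06 for B cells and 2.17e-09 for T cells, and these calls were lost with an estimated correlation (adjusted p = 0.740 and 0.522), a setting added after seeing the data. The calls of lymph node stroma, NK cells and dendritic cells were lost on plate 1 at the preset correlation (adjusted p 0.0575, 0.166 and 0.209). By fry, which tests whether the genes of a list move one way without comparing them with other genes, the adjusted p was 0.670 for the B cell, T cell and lymph node stroma lists.

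In cluster 3 the B cell, T cell and lymph node stroma list means lay between those of the other 2 clusters, by less than their errors. The B cell list mean differed by 0.069 (SE 0.21) from cluster 1 and by −0.16 (SE 0.20) from cluster 2, and the T cell list mean by 0.072 (SE 0.21) and −0.16 (SE 0.20). On plate 1 alone, with 9 mice of cluster 3, the B and T cell differences from cluster 2 were −0.017 (SE 0.22) and −0.015 (SE 0.22). Those from cluster 1 were 0.11 (SE 0.23) and 0.14 (SE 0.23) there. Against cluster 1, Ms4a1 differed by 0.13 (SE 0.31), Tnfrsf13c by 0.079 (SE 0.20), Trat1 by 0.12 (SE 0.23), Cd3e by 0.13 (SE 0.25), Glycam1 by 0.18 (SE 0.36), Ccl19 by 0.12 (SE 0.25), Pnpla2 by −0.016 (SE 0.10) and Slc2a4 by −0.026 (SE 0.18). Against cluster 2, Cxcr5 differed by −0.17 (SE 0.19), Fcrla by −0.19 (SE 0.21), Cd2 by −0.18 (SE 0.20), Cd3d by −0.19 (SE 0.22), Ltb by −0.16 (SE 0.19), Cxcl13 by −0.22 (SE 0.29), Fabp4 by 0.015 (SE 0.059) and Aqp7 by 0.040 (SE 0.16). Camera called 4 lists against cluster 1 and 6 against cluster 2, and 0 of these calls held with an estimated correlation, where the adjusted p of the B cell list was 0.983 and 0.399.

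Limma called 0 of 28204 probe sets in each of the 3 cluster comparisons. At an unadjusted p under 0.05 there were 4 probe sets for cluster 2 against 1, 1 for 3 against 1 and 1 for 3 against 2. These are 0.0142%, 0.0035% and 0.0035% of the probe sets, and random splits of the same mice gave at least 1.60%, 1.09% and 1.38%. The real clusters thus lay below all 99 random splits in each comparison.

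**Figure D1:**
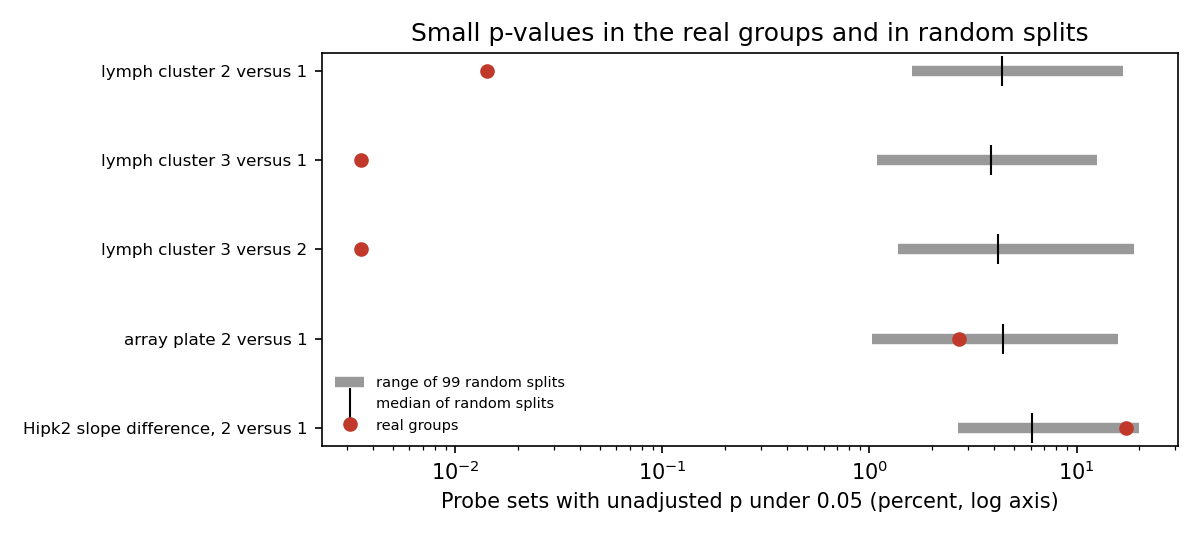
The horizontal axis is the percentage of probe sets with an unadjusted p under 0.05, on a log axis, for 5 comparisons, with red points for the real groups, grey bars for the range of 99 random splits and black ticks for their median. The 3 cluster comparisons lie at 0.0142%, 0.0035% and 0.0035%, below the bars, and array plate at 2.70% lies within its bar.

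Between array plates, the ribosomal protein gene Rpl39 was lower on plate 2 by 0.128 on the log2 scale (log2 difference −0.128, SE 0.026, limma adjusted p 0.0279, 22 against 93 arrays). Limma called 3 probe sets, 1 higher and 2 lower, and Rpl39 was the 1 named gene among them. The B cell list mean differed by 0.15 (SE 0.14) and the oxidative phosphorylation list mean by −0.082 (SE 0.076). Camera called 8 lists, and 0 with an estimated correlation, where the adjusted p was 0.496 for both. Hipk2 differed by −0.006 (SE 0.083) between plates. The count of calls was 27 after quantile normalization was repeated, 8 with centred arrays and 1 with array weights, where the adjusted p of Rpl39 was 0.0760 (range over alternatives 0.0050 to 0.0760).

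The second question was which genes varied with Hipk2 from mouse to mouse. White adipocyte genes rose with Hipk2: all 18 measured members were called, and the list mean rose by 0.70 (SE 0.042, n = 115) per log2 unit of Hipk2. Aqp7, a glycerol channel, rose by 1.15 (SE 0.066), Plin1, a lipid droplet coat protein, by 0.70 (SE 0.044), the hormone gene Lep by 1.39 (SE 0.17) and Adipoq by 0.66 (SE 0.050). The adipogenic transcription factors Pparg and Cebpa rose by 0.68 (SE 0.059) and 0.74 (SE 0.066), and the fatty acid carrier Fabp4 by 0.33 (SE 0.035). The casein genes Csn1s1, Csn1s2a and Csn2 were among the 8 largest falls, with slopes of −2.51 (SE 0.60) for Csn1s1, −2.03 (SE 0.55) for Csn1s2a and −1.95 (SE 0.47) for Csn2. Limma's adjusted p for these genes ranged from 7.24e-30 for Aqp7 to 0.0015 for Csn1s2a. Other milk protein genes, named after their values were seen, were mixed: Wap fell by 0.84 (SE 0.27, adjusted p 0.008), while Csn3 had a slope of −0.52 (SE 0.27, adjusted p 0.123), Csn1s2b −0.13 (SE 0.062, adjusted p 0.090) and Lalba −0.17 (SE 0.42, adjusted p 0.811).

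Limma called 10083 of 28203 probe sets for the slope, 5226 rising and 4857 falling, from 7604 of 18771 genes. Of these, 124 rose and 22 fell by at least 2-fold per log2 unit of Hipk2. The 8 largest rises were Mest with a slope of 2.28 (SE 0.34), S100b 2.19 (SE 0.46), Prr32 1.95 (SE 0.20), Slc6a13 1.87 (SE 0.23), Alb 1.83 (SE 0.22), Sfrp5 1.77 (SE 0.29), Rnase2a 1.72 (SE 0.45) and Timp4 1.71 (SE 0.15). Mest and Sfrp5 are genes known from expanding adipose tissue. Besides the 3 casein genes, the 8 largest falls were Tph1, the first enzyme of serotonin synthesis, with −1.59 (SE 0.35), Muc15 −1.29 (SE 0.37), the gap junction gene Gjb2 −1.20 (SE 0.32), Atp1b1 −1.16 (SE 0.14) and Pdlim3 −1.13 (SE 0.30).

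Other lists of fat metabolism were mixed. Of 18 lipid synthesis genes 12 rose and 6 were not called, with a list mean of 0.38 (SE 0.083; adjusted p = 0.661 with an estimated correlation). Dgat2 and Dgat1, which make triglyceride, rose by 0.65 (SE 0.056) and 0.70 (SE 0.078), and the fatty acid synthase gene Fasn by 0.32 (SE 0.081). Of 28 oxidative phosphorylation genes 14 rose, among them Atp5b by 0.23 (SE 0.044) and Ndufb8 by 0.51 (SE 0.11), with a list mean of 0.22 (SE 0.084; adjusted p = 0.806 with an estimated correlation). Of 14 brown adipocyte genes 3 rose, among them Prdm16 by 0.59 (SE 0.070) and Otop1 by 1.03 (SE 0.20), with a list mean of 0.28 (SE 0.23; camera adjusted p 0.286). With the white adipocyte list mean as a covariate, chosen after seeing the data, Fasn and Ndufb8 were called with the opposite sign, at −0.44 (adjusted p 0.0169) and −0.53 (adjusted p 0.0313), and Dgat2, Dgat1, Atp5b and Otop1 also turned negative without being called. Ucp1, the uncoupling protein of brown fat, had a slope of 0.48 (SE 0.55, adjusted p 0.558). Of 8 adipocyte progenitor genes 3 rose and 2 fell, with Zfp423 at 0.66 (SE 0.054) and Cd24a at −0.89 (SE 0.13), and a list mean of 0.053 (SE 0.059).

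Of 12 blood endothelium genes 11 rose, with Flt1, a receptor of vascular endothelial growth factor, at 0.69 (SE 0.065), Esam at 0.81 (SE 0.078) and a list mean of 0.55 (SE 0.059; adjusted p = 0.206 with an estimated correlation). Of 12 fibroblast and matrix genes 7 rose, with Sparc at 0.44 (SE 0.049), Col6a1 at 0.60 (SE 0.085) and a list mean of 0.21 (SE 0.080; adjusted p = 0.806 with an estimated correlation). Of 5 Schwann cell genes 3 rose and 1 fell, with Pmp22 at 0.57 (SE 0.066) and a list mean of 0.57 (SE 0.11). S100b, among the largest rises above, is also in this list and raises its mean, and the median slope of the list was 0.570.

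Camera called the luminal epithelium, cell cycle, T cell, B cell, NK cell and lymph node stroma lists lower, and each of these calls was lost with an estimated correlation (adjusted p = 0.661 for the cell cycle, T cells and lymph node stroma, and 0.723 for luminal epithelium, B cells and NK cells). By fry each of these lists passed, with an adjusted p from 3.49e-06 for the cell cycle to 0.0106 for NK cells. Of 21 luminal epithelium genes 16 fell, with Cldn7 at −0.82 (SE 0.19), Ehf at −1.08 (SE 0.26) and a list mean of −0.76 (SE 0.20). All 21 cell cycle genes fell, with the replication licensing genes Mcm2 and Mcm4 at −0.70 (SE 0.097) and −0.56 (SE 0.088) and a list mean of −0.63 (SE 0.12). All 16 T cell genes fell, with Cd3g at −1.04 (SE 0.20), Trat1 at −0.76 (SE 0.16) and a list mean of −0.64 (SE 0.15), although in cluster 1 alone the T cell list mean had a slope of 0.04 (SE 0.21), against −0.97 (SE 0.18) in cluster 2 alone. Of 18 B cell genes 13 fell, with Pax5 at −0.58 (SE 0.17), Pou2af1 at −0.46 (SE 0.13) and a list mean of −0.49 (SE 0.15). The B cell list mean had a slope of −0.11 (SE 0.21) in cluster 1 alone and −0.58 (SE 0.20) in cluster 2 alone, a difference of −0.47 (SE 0.30; adjusted p = 0.731 with an estimated correlation). Of 12 NK and cytotoxic genes 6 fell, with Ctsw at −0.53 (SE 0.13) and Nkg7 at −0.49 (SE 0.16), and a list mean of −0.24 (SE 0.077). Of 9 lymph node stroma genes 6 fell, with Ltb at −0.71 (SE 0.14), Glycam1 at −1.02 (SE 0.26) and a list mean of −0.43 (SE 0.10). Which cells of the fat pad gave the Glycam1 signal was not tested. In clusters 1 and 2 alone the list mean slopes were 0.05 (SE 0.11) and −0.39 (SE 0.10) for NK cells, −0.11 (SE 0.16) and −0.52 (SE 0.12) for lymph node stroma, −1.05 (SE 0.38) and −0.61 (SE 0.25) for luminal epithelium and −0.51 (SE 0.24) and −0.69 (SE 0.15) for the cell cycle.

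Besides the brown adipocyte, adipocyte progenitor and Schwann cell lists, the lists that follow were not called by camera. The slope was −0.46 (SE 0.46) for the skeletal muscle list mean, with 0 of 18 genes called, Myh2 at −1.01 (SE 0.45) and Mb at −0.88 (SE 0.45), and it was −1.97 (SE 0.74) in cluster 1 alone and 0.18 (SE 0.62) in cluster 2 alone. Of 6 basal epithelium genes 1 fell, and the list mean had a slope of −0.38 (SE 0.20), with Trp63 at −0.37 (SE 0.14) and Krt15 at −0.58 (SE 0.27, adjusted p 0.0812). Of 14 macrophage genes 3 rose and 1 fell, with a list mean of 0.13 (SE 0.092), Mertk at 0.40 (SE 0.080) and Cd163 at 0.49 (SE 0.15). Of 8 dendritic cell genes 3 fell, with a list mean of −0.14 (SE 0.074), Flt3 at −0.43 (SE 0.12) and Itgax at −0.26 (SE 0.098). The dendritic cell list mean rose in cluster 1 alone, by 0.26 (SE 0.10), and fell in cluster 2 alone, with a slope of −0.38 (SE 0.10). Of 8 plasma cell genes 1 rose and 2 fell, with a list mean of −0.046 (SE 0.052), Tnfrsf17 at 0.26 (SE 0.082) and Mzb1 at −0.30 (SE 0.11). Of 9 granulocyte genes 2 rose and 1 fell, with a list mean of −0.022 (SE 0.052), Elane at 0.25 (SE 0.072) and Cxcr2 at −0.37 (SE 0.12). Of 6 lymphatic endothelium genes 1 rose and 1 fell, with a list mean of −0.089 (SE 0.086), Pdpn at −0.45 (SE 0.089) and Flt4 at 0.44 (SE 0.091).

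The Wnt, p53, Hipk partner and immediate early lists held genes that moved both ways. Of 12 Wnt targets 2 rose and 4 fell, with Apcdd1 at 0.96 (SE 0.099), Rnf43 at −0.72 (SE 0.12) and a list mean of −0.098 (SE 0.033). Of 13 p53 targets 3 rose and 4 fell, with Sesn2 at 0.63 (SE 0.090), Phlda3 at 0.66 (SE 0.10) and a list mean of 0.11 (SE 0.025). Of 13 genes of the Hipk family and its partners 3 rose and 3 fell, with Hipk3 at 0.49 (SE 0.059), Hipk1 at 0.13 (SE 0.037) and a list mean of 0.003 (SE 0.024), where camera's direction was down. Of 13 interferon response genes 3 fell, with a list mean of −0.22 (SE 0.12), Zbp1 at −0.62 (SE 0.12) and Usp18 at −0.47 (SE 0.16). Of 13 immediate early and heat shock genes 2 rose and 4 fell, with a list mean of −0.028 (SE 0.063) against a median slope of 0.042, Dusp1 at 0.49 (SE 0.12) and Junb at −0.23 (SE 0.066). Of 3 measured erythroid genes 1 rose, with a list mean of 0.17 (SE 0.048), Alas2 at 0.46 (SE 0.099) and Epb42 at 0.050 (SE 0.047, adjusted p 0.459).

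**Figure D2:**
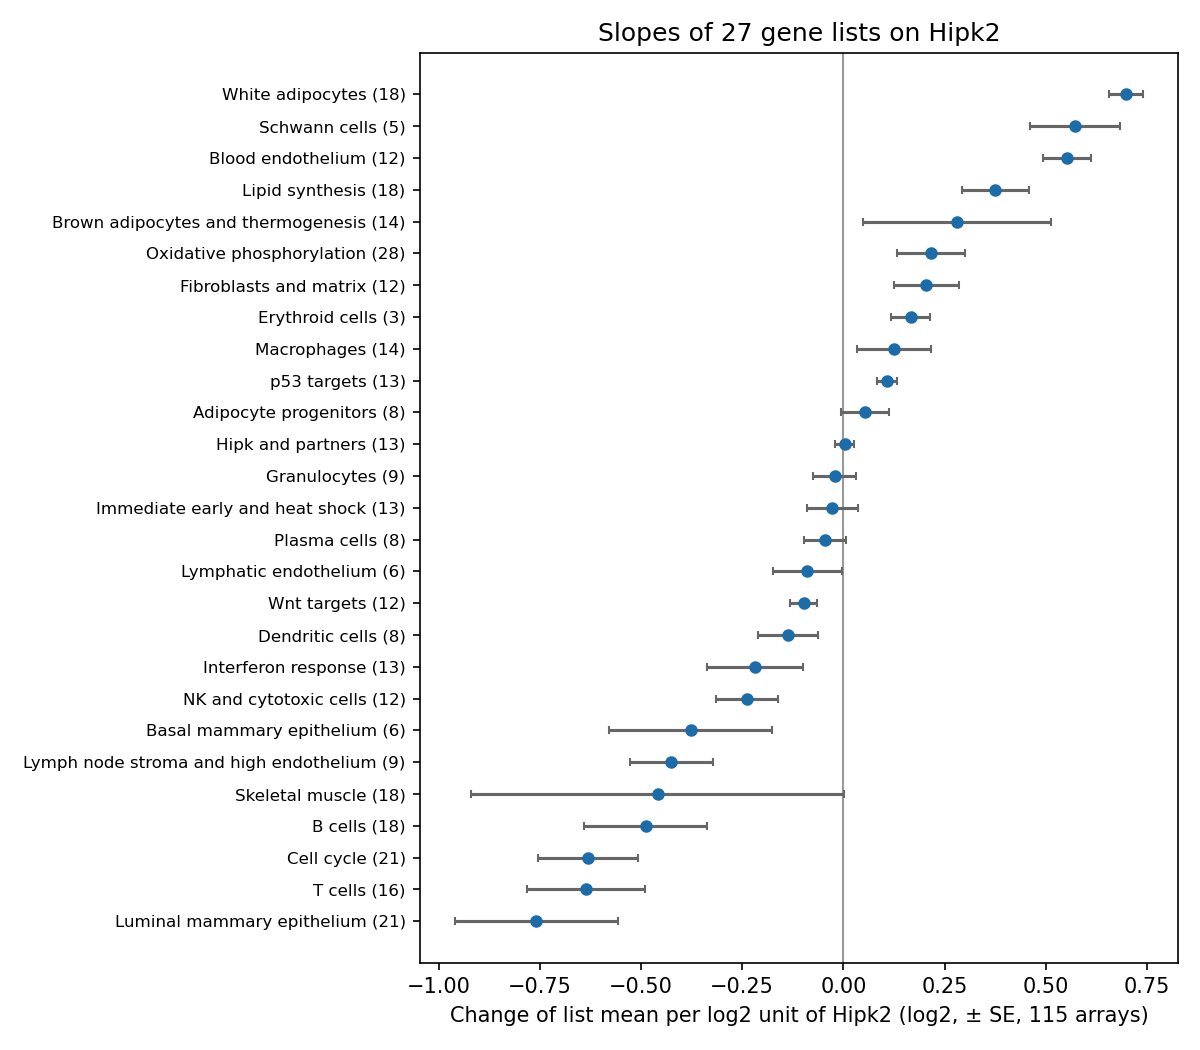
The horizontal axis is the change of each list mean per log2 unit of Hipk2, on the log2 scale, for 27 gene lists with the number of measured genes in brackets (points, slopes over 115 arrays, and bars, standard errors). White adipocytes lie highest at 0.698 and luminal epithelium lowest at −0.759.

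Camera called 11 lists for the slope, 5 rising and 6 falling. The adjusted p was 8.84e-26 for white adipocytes, 1.56e-09 for the cell cycle and 1.34e-08 for blood endothelium. With an estimated correlation the white adipocyte list alone was called, with an adjusted p of 0.0015. The calls of the other 10 lists were lost with it. By fry all 11 lists passed, with an adjusted p from 1.02e-31 for white adipocytes to 0.0173 for oxidative phosphorylation. Fry also passed the Schwann cell, adipocyte progenitor, erythroid and p53 lists. Unlike camera, fry does not compare a list with other genes, of which many varied with Hipk2. Adjusted over the list alone, 18 white adipocyte genes, 13 lipid synthesis genes, 16 oxidative phosphorylation genes and 11 blood endothelium genes rose, and 16 T cell, 16 B cell, 16 luminal and 21 cell cycle genes fell. Counted in that way 1 luminal gene rose, 2 dendritic cell genes rose and 5 fell, 0 basal and 2 interferon response genes fell, and the other lists gave the counts stated above.

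Fewer probe sets were called once the white adipocyte list was in the model. With its mean as a covariate, chosen after seeing the data, 2606 probe sets were called. They held 1440 of the 10083 calls, 1176 with the same direction and the others with the opposite one. Among the genes named above, the slopes of Pparg, S100b, Tph1, Muc15, Cldn7, Ehf, Pou2af1, Ctsw, Nkg7, Mzb1, Cd163, Itgax, Elane, Cxcr2, Cd24a, Trp63, Krt15, Epb42, Junb, Phlda3, Rnf43 and Ucp1 also changed sign with it, and none of these was then called. Pparg is itself a member of the white adipocyte list. With the list mean in the model the slopes of its members must cancel out, so the sign change of Pparg is no separate result. Plate 2 alone gave 920 calls and cluster 1 alone 4891. With arrays centred on their median, 6697 probe sets rose and 3704 fell.

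Within clusters, the correlation of Hipk2 with Plin1 was r = 0.840 (rho 0.835) in cluster 1, 0.834 (rho 0.869) in cluster 2 and 0.802 (rho 0.539) in cluster 3. In clusters 1 and 2 the permutation p for r and rho was 1e-05, the smallest the permutations can give, and the adjusted p was 2e-05 for r and 3e-05 for rho. In cluster 3 the permutation p was 0.00564 for r (adjusted 0.00902) and 0.115 for rho (adjusted 0.145, n = 10). For Adipoq r was 0.781, 0.771 and 0.893 in clusters 1, 2 and 3 (permutation p 1e-05, 1e-05 and 0.00059, adjusted 2e-05, 2e-05 and 0.00109). Its rho was 0.674, 0.788 and 0.867 (permutation p 2e-05, 1e-05 and 0.00224, adjusted 5.33e-05, 3e-05 and 0.00384). Ucp1 gave r of −0.050, 0.205 and −0.323 (permutation p 0.745, 0.114 and 0.367, adjusted 0.778, 0.137 and 0.4) and rho of −0.073, 0.175 and −0.370 (permutation p 0.638, 0.176 and 0.294, adjusted 0.658, 0.211 and 0.336). Of 24 relations with 8 genes, 16 passed by r and 14 by rho.

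Within array plate 1, 16 of 24 relations passed by r and 15 by rho, and within plate 2, 9 of 16 passed by r and 3 by rho. Within plate 1 the r of Plin1 was 0.907, 0.877 and 0.783 in the 3 clusters, and within plate 2 it was 0.822 and 0.725 in clusters 1 and 2. The r of Adipoq was 0.805, 0.788 and 0.874 within plate 1 and 0.774 and 0.721 within plate 2. The r of Ucp1 was 0.090, 0.035 and −0.154 within plate 1, and −0.445 and 0.716 within plate 2, where the relation in cluster 2 passed by r (permutation p 0.014, adjusted 0.0281, n = 11) and not by rho (adjusted 0.0576). Cluster 3 has 1 array on plate 2, so it gave no value there. Without the 2 arrays farthest from the median Hipk2, 13 of 24 passed by r and 13 by rho. There r was 0.815, 0.801 and 0.264 for Plin1, 0.724, 0.727 and 0.633 for Adipoq and 0.051, 0.220 and −0.238 for Ucp1. In cluster 3 the relation of Plin1 thus rests on those 2 arrays (adjusted exact permutation p 0.63 without them, n = 8). For Adipoq in cluster 3, r was 0.633 (exact permutation p 0.101, adjusted 0.151) and rho 0.738 (exact permutation p 0.0458, adjusted 0.0786) on those 8 mice, which no longer passed.

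**Figure D3:**
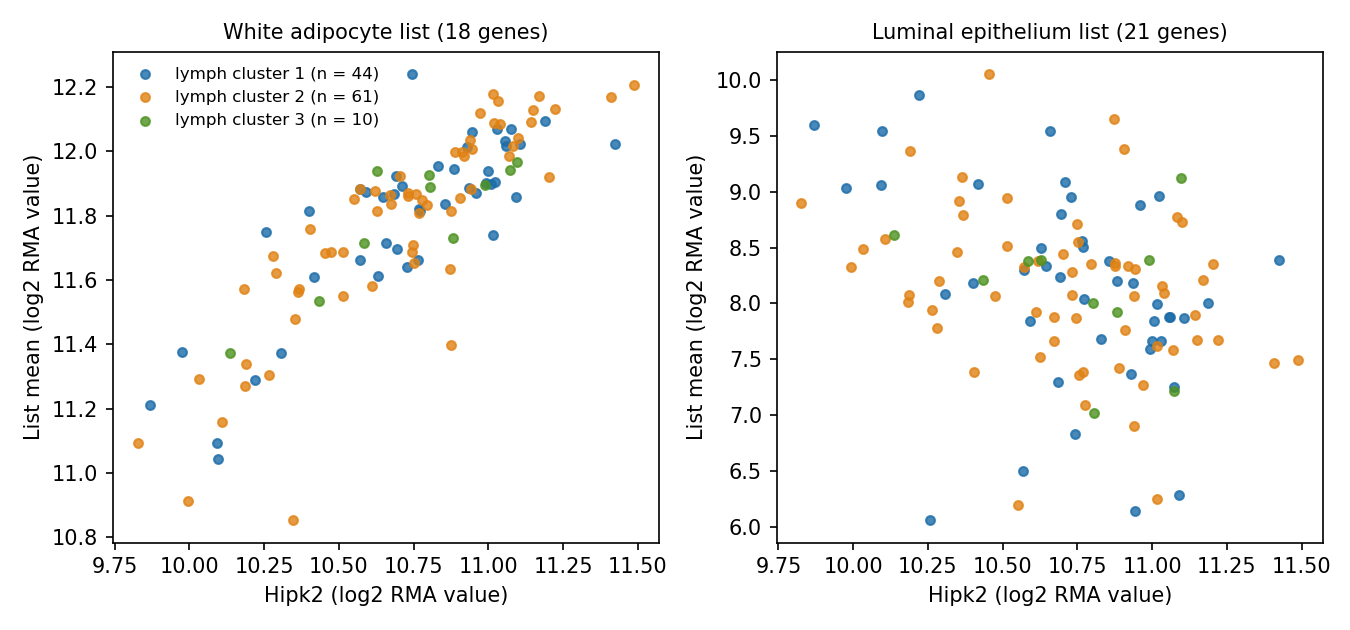
The horizontal axis is the log2 RMA value of Hipk2 and the vertical axis the mean log2 value of 18 white adipocyte genes (left) or 21 luminal epithelium genes (right), with 1 point per mouse coloured by lymph cluster (n = 44, 61 and 10). The white adipocyte mean rises with Hipk2 and the luminal mean falls with more scatter.

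Genes near Hipk2 on its chromosome were called less often than other genes. Of 323 genes within 20 Mb of Hipk2 in the RefSeq table of assembly GRCm38.p6, 111 (34.4%) were called for the slope, against 7382 of 18421 genes elsewhere (40.1%). The odds ratio was 0.783 (95% interval 0.615 to 0.992, Fisher's exact test p = 0.039). Within 10 Mb the odds ratio was 0.657 (95% interval 0.473 to 0.903, p = 0.007), and over the whole chromosome it was 0.925 (p = 0.242). The genes near Hipk2 and elsewhere were not matched on level, and why fewer were called near it was not tested. Genes are not independent replicates in this comparison.

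The third question was whether slopes on Hipk2 differed between clusters 1 and 2. Several T cell and dendritic cell genes had lower slopes on Hipk2 in cluster 2 than in cluster 1. The T cell list mean had a slope of 0.04 (SE 0.21, n = 44) in cluster 1 and −0.97 (SE 0.18, n = 61) in cluster 2, a difference of −1.02 (SE 0.28; adjusted p = 0.409 with an estimated correlation), and 11 of 16 genes were called lower. The dendritic cell list mean had slopes of 0.26 (SE 0.10) and −0.38 (SE 0.10), a difference of −0.64 (SE 0.15; adjusted p = 0.287 with an estimated correlation), and 4 of 8 genes were called lower. Of 28 oxidative phosphorylation genes 2 were called higher, and the list mean had slopes of −0.08 (SE 0.15) and 0.40 (SE 0.10), a difference of 0.48 (SE 0.18; adjusted p = 0.409 with an estimated correlation). Of 18 skeletal muscle and 14 brown adipocyte genes 0 were called, and their list means differed by 2.16 (SE 0.98) and 1.01 (SE 0.50), with an adjusted p of 0.494 for both with an estimated correlation. The white adipocyte list mean had slopes of 0.65 (SE 0.07) and 0.74 (SE 0.06), with a difference of 0.094 (SE 0.091) and 0 genes called. Limma called 1302 probe sets, 127 with a higher and 1175 with a lower slope in cluster 2, with 148 differing by at least 2-fold, and camera called 11 lists, 5 higher and 6 lower. With an estimated correlation camera called 0 lists.

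The slope difference depended on few arrays. Without the 10 arrays with the widest deviations from the probe set medians, a choice made after seeing the data, 4 probe sets were called. Without replicate 3 of cluster 1 alone, 696 were called, and plate 1 alone gave 156.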

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

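The tests of cluster means adjusted before deposit, of clusters that do not differ or are alike in lymphoid content, and of other splits for the cluster and plate comparisons were chosen after the result was seen. The test of lymphoid content was set out first and gave a mixed answer, so that of clusters that do not differ was added later, and both are given.

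Of 36 gene and list values in cluster 3, where 10 mice were compared, 2 had 1 mouse far from the others, and chance gives about 1 in 20. The immediate early list mean was 8.06 in replicate 2, against 7.50 for the next mouse. In the same mouse Fasn was lowest at 11.97, against 12.38 for the next.

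Of 76 genes named for the slope, 4 had slopes on Hipk2 that differed between clusters 2 and 1 by limma's test of the difference. That test called 4.62% of all 28203 probe sets, so 4 of 76 is near the share over all probe sets. Flt3 differed by −1.15 (SE 0.23, adjusted p 6.64e-04), Trat1 by −1.08 (SE 0.31, adjusted p 0.0253), Ctsw by −0.83 (SE 0.25, adjusted p 0.0329) and Itgax by −0.73 (SE 0.20, adjusted p 0.0146). The count of calls, 1302, was reached by 1 of 100 splits of the mice, the real one, and the highest other split gave 836. The real split thus had the highest count of the 100, but not the highest share of small p-values. Its 17.3% of probe sets with an unadjusted p under 0.05 lay below the 19.9% of the highest random split. The count was 696 without replicate 3 of cluster 1 and 4 without the 10 widest arrays. Chance is therefore not excluded.

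Small p-values between lymph clusters 1 and 2 were rarer than in random splits of the same mice, at 0.0142% of probe sets. Clusters that simply do not differ, or too little power, would give a share like that of random splits of equal size, whose lowest was 1.596%, and 95.7% of simulated changes of 0.5 log2 but 67.3% of those of 0.25 were recovered. The share of probe sets with unequal variance was 2.287%, below the lowest random split at 5.836%, so an adjustment of cluster means and spread before deposit may explain both and stays open, since no source used here records one. Whether lymphoid content was alike could not be decided: the median B cell difference of 0.228 exceeded all random splits (highest 0.194), and the T cell difference of 0.222 did not (highest 0.280). A biological difference between clusters stays undecided. If the values were adjusted for cluster before deposit, limma, camera, fry and random splits above cannot test it. If the clusters were made from these expression values, a lymphoid difference beyond that of random splits is no independent evidence.

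For each cluster comparison the real count was 0 calls, which any split reaches (100 of 100 splits), so counting splits tests nothing there, and the highest other split gave 1 for 2 versus 1, 9 for 3 versus 1 and 10 for 3 versus 2. Between plates 2 of 100 splits, the real one included, gave as many as the real 3 calls. The share of 2 in 100 lies under 0.05. However, the highest other split gave 4 calls, more than the real one. Only 19 of 99 gave no more small p-values than the real 2.70%, so chance is not excluded.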

How the results depend on the processing

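The alternatives without the 10 arrays of widest deviation, single arrays left out of the slope difference, the white adipocyte covariate, the quality covariates, and 2 of the slope difference settings (no plate term, composition covariates) were added after seeing the data, as was leaving the 2 farthest arrays out of that comparison. No paired analysis was possible because the replicate numbers follow accession order and each mouse gave 1 array. No other probe set named Hipk2 with 1 symbol was present, so that alternative gave no value. The cause of each change below was not tested, except that fewer arrays were tested where plates or clusters stood alone.

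The counts of calls in the cluster comparisons stayed at 0 in all settings, with 1 exception: 3 versus 1 on plate 2 alone gave 1 call. The plate comparison gave 27 calls after repeated quantile normalization, 8 with centred arrays and 1 with array weights. The Hipk2 slope gave 920 calls on plate 2 alone, 4891 in cluster 1 alone and 2606 with the white adipocyte covariate, and from 7644 to 10401 in the other settings. The slope difference gave 156 calls on plate 1 alone, 828 with normal scores, 417 with composition covariates and 4 without the 10 widest arrays, and single arrays left out gave 696 to 1338. Without replicate 3 of cluster 1 it gave 696.

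With an estimated correlation, camera called 5 lists for cluster 2 versus 1, 0 for 3 versus 1, 0 for 3 versus 2, 0 for plate, 1 for the slope and 0 for the slope difference. On plate 1 alone at the preset correlation it called 4 lists for 2 versus 1 and 1 for 3 versus 2. On plate 1 alone with an estimated correlation, added after seeing the data, it called 0 for 2 versus 1, 0 for 3 versus 1, 0 for 3 versus 2, 1 for the slope and 0 for the slope difference. The odds ratio of the Hipk2 neighbours was 0.925 over the whole chromosome, no longer past the threshold. Hipk2 correlations passed in 9 of 16 relations by r within plate 2, and in 3 by rho.

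Some values changed sign. Hipk2 differed by 0.004, −0.014 and −0.018 between clusters (2 versus 1, 3 versus 1, 3 versus 2) on plate 1 alone. None of the cluster genes below was called in any setting. On plate 1 alone, Cd36 was 0.003 for 2 versus 1, Pnpla2 0.053 and Slc2a4 0.046 for 3 versus 1, and Fabp4 −0.012 and Aqp7 −0.015 for 3 versus 2. For 3 versus 1 on plate 2 alone, with 1 array of cluster 3, Ms4a1 was −0.933, Tnfrsf13c −0.624, Trat1 −0.527, Cd3e −0.798, Glycam1 −1.651 and Ccl19 −0.994. Repeated quantile normalization gave Pnpla2 6.57e-04. Array weights gave Cxcl13 0.016, Fabp4 −0.027 and Aqp7 −0.009 for 3 versus 2. Normal scores gave Ms4a1 −0.025, Cd3e −0.059 and Ccl19 −0.064 for 3 versus 1, and Aqp7 −0.030 for 3 versus 2. Without the 10 widest arrays Pnpla2 was 0.034 and Slc2a4 0.030 for 3 versus 1, and Fabp4 −0.018 and Aqp7 −0.030 for 3 versus 2.

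For the Hipk2 slope, Epb42 was −0.063 on plate 2 alone. In cluster 1 alone Ctsw was 0.021, Nkg7 0.165, Flt3 0.305, Itgax 0.178, Epb42 −0.010 and Ucp1 −0.310. With the white adipocyte covariate the slopes that changed sign were S100b −0.322, Tph1 0.556, Muc15 0.646, Pou2af1 0.184, Ctsw 0.012, Nkg7 0.006, Mzb1 0.386, Cd163 −0.285, Itgax 0.136, Elane −0.075, Cxcr2 0.017, Dgat2 −0.016, Dgat1 −0.069, Otop1 −0.802, Cd24a 0.176, Cldn7 0.182, Ehf 0.433, Trp63 0.433, Krt15 0.140, Epb42 −0.093, Junb 0.179, Atp5b −0.180, Ndufb8 −0.528, Rnf43 0.224, Phlda3 −0.427, Pparg −0.069, Fasn −0.437 and Ucp1 −2.444. Among these, Ndufb8 and Fasn were called with the new sign (adjusted p 0.0313 and 0.0169), and Pparg is a member of the list that gave the covariate. Single correlations that changed sign were Ucp1 in cluster 1, with 0.090 within plate 1 and 0.051 without the 2 farthest arrays, Fasn in cluster 3 with 0.074 within plate 1, and Cebpa in cluster 3 with −0.225 without the 2 farthest arrays. Of the other values for single genes of the slope, 1143 kept their direction and side of the threshold, 170 no longer passed and 10 newly passed. Signal over background was not analysed here, so its limit on dim probe sets is open.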

Other observations

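The tests with levels at least 3 SD apart were chosen after the stricter limit of 4 SD had given too few genes.

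Skeletal muscle genes were the most variable list from mouse to mouse, with a list mean of 7.17 ± 1.69 (SD, n = 115) and a range from 5.10 to 12.42. Brown adipocyte genes ranged from 6.06 to 9.91 (SD 0.85), and Ucp1 from 4.94 to 12.64. The brown adipocyte mean followed the oxidative phosphorylation mean, with r = 0.92 (rho 0.89) in cluster 1 and r = 0.85 (rho 0.84) in cluster 2. The permutation p was 1e-05 for each, the smallest the permutations can give (adjusted 4.5e-05), and without the 2 farthest mice r was 0.90 and 0.82. In cluster 3 r was 0.25 (rho 0.18, permutation p 0.489 and 0.614, n = 10). These were 2 of 18 relations among list means, chosen after the lists had been seen, and r was 0.93 and 0.85 within plate 1 and 0.91 and 0.90 within plate 2 (adjusted permutation p 6e-05, 6e-05, 0.00146 and 0.00107 among 30 relations).

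The array values of some genes fell into 2 separated levels across the mice, as a gene near a strain difference would in a backcross. Whether such levels reflect expression, or how well the array probes match the Mus spretus sequence, was not tested. Among 18745 genes, 21 had levels at least 4 SD apart with at least 30% of mice at each, and 0 of 2000 simulated normal genes did. Because the simulated genes were normal, they cannot tell a strain difference from skewed values. The skeletal muscle list was skewed, with a mean of 7.20 and a median of 6.12 in cluster 1, and its members Ckm and Atp2a1 were among the 21. The widest separation in SD units, 6.50, was that of Cdh9, a cadherin, with levels 2.87 apart on the log2 scale and 56.7% of mice at the lower one. Mrps28, of the mitochondrial ribosome, had 51.3% at the lower level, Mgst2 53.1% and H2-Ea, a class II antigen presentation gene, 52.9%. S100b, among the largest rises with Hipk2, had levels 3.48 apart and 38.9% of mice at the lower one, and Ckm, a muscle gene, had 70.0%. These genes were named after their values were seen.

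Genes with 2 levels near each other on a chromosome varied together across mice. With the 4 SD limit the test of linked Mus spretus blocks rested on 1 pair 10 to 20 Mb apart (squared correlation 0.692), and 0 pairs lay 1 to 5 Mb apart, so neither linkage nor shared probes could be decided. With 80 genes at the looser limit, the mean squared correlation was 0.373 (jackknife SE 0.056, 31 pairs) 10 to 20 Mb apart and 0.021 (SE 0.004) on different chromosomes, consistent with linked Mus spretus blocks. Pairs 1 to 5 Mb apart gave 0.390 (SE 0.140), from 14 pairs, too few under the limit of 20 to decide on probe sets that share probes. Squared correlation fell to 0.057 (SE 0.035) over 80 Mb.

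Many probe sets varied with Hipk2, and 5 explanations were tested. Array quality is argued against by 9767 calls with the array median and deviation width as covariates. Chance pairing is argued against by 1 of 100 pairings of Hipk2 with mice, the real one, giving as many calls (highest other 0). Within 20 Mb of Hipk2 lay 1.48% of the called genes. That share could not decide on linked genes, since 323 genes lie there against 7382 called elsewhere, so it had to be small. Genes there were called at 34.4%, against 40.1% elsewhere. Adipocyte share was examined on 14 lists of other cell types with at least 6 measured genes. The smaller Schwann cell and erythroid lists were not counted, and their means rose by 0.57 (SE 0.11) and 0.17 (SE 0.048). Of the 14 lists, 5 fell with Hipk2 by over 2 SE, as adipocyte share would give. Another 7 lay within 2 SE, which the test allowed but which shows no fall, as for macrophages at 0.13 (SE 0.092). The means of 2, blood endothelium and fibroblasts, rose by over 2 SE, which argues against adipocyte share as the whole cause. Neither of these 2 was called by camera with an estimated correlation. Vessels and matrix are also part of fat, so the share of fat tissue as a whole stays open. The number of calls is not particular to Hipk2: among 100 predictors, Hipk2 and 99 probe sets of like level and spread, 25 gave as many calls (median of the 99, 9005, highest 12094). Hipk2 ranked 61 of 18754 genes by its partial correlation of 0.846 with the white adipocyte list mean, so it may be 1 of many genes that track fat content, and these data do not separate cause from company.

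With the 4 SD limit 0 genes with 2 levels lay within 20 Mb of Hipk2. With the 3 SD limit 1 gene did, and its absolute correlation with Hipk2 was 0.450 (adjusted p 8.72e-06), against a 95th percentile of 0.448 on other chromosomes. Of all 80 such genes 30 passed the same test, and the largest correlation was 0.738 for Slc24a3.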
